A study of Mus musculus with 6 samples.

How the data were processed

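Total RNA of microdissected olfactory epithelium was analysed from 6 mice, 3 hemizygous Harlequin males and 3 wild-type male littermates. Per the labels' protocols, the mice arrived at 13 weeks of age and were kept to 6 months, tissue was snap-frozen, RNA was purified and checked for integrity, and biotin-labelled cRNA was made from 3 µg of total RNA by the manufacturer's procedure. The labels describe the arrays of a genotype as biological replicates. The titles call the controls littermates, and the strain field differs between the genotypes, with B6CBACAw-J/A-Pdcd8-Hq/J for Harlequin and B6CBACa for controls, so any difference in strain background and the genotype share the same split of the arrays. The groups and replicate numbers were taken from the sample titles.

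The deposited values are linear probe set intensities, 45101 per array, between 0.1 and 31786 and given to 1 decimal. The mean over each array after leaving out the lowest and highest 2% was 500 on all 6 arrays, as after scaling each array by a single factor, and no further normalization between arrays was visible in the values. The software that condensed probe cells into these intensities was not given in the sources used here. A single factor per array leaves intensity-dependent differences between arrays in place. Quantile normalization and median scaling were therefore run as alternatives.

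The values were analysed as log2(value + 16), which understates changes of dim genes. The 64 control probe sets were left out. Of the other 45037 probe sets, 34945 name 1 gene in the platform annotation, 932 name several and 9160 are unnamed in the table used here. Names were updated through gene identifiers against a RefSeq gene table, in which 18032 of 18194 identifiers were found and 0 symbols changed. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays. Genes were kept where that mean lay above the 40th percentile of all non-control probe sets, a signal of 61.1, which left 13219 genes. Probe sets naming several genes or none were tested separately and are described without gene names.

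Harlequin was compared with control in limma 3.58.1 (R 4.3.3) with lmFit and empirical Bayes moderation that follows the intensity trend, 3 against 3 arrays, without further terms. P-values are two-sided and adjusted by the Benjamini-Hochberg method, and genes under 0.05 are called changed. Fold changes are Harlequin over control on the log2(value + 16) scale, and intervals cover 95%. The Aifm1 difference was also tested by an exact permutation test. The order of the genes along each chromosome came from the RefSeq table and served only to find neighbours. Summaries were made in Python 3.11.15 with pandas 2.3.3 and figures with matplotlib 3.10.9.

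Before the data were examined, 34 lists of cell type markers and pathway genes, the tests, the alternatives and the rule for named genes were fixed. Of 617 listed symbols, odorant receptors aside, 561 were on the array. Lists with at least 5 measured genes, 31 in all, were tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists, and members were also adjusted over the list alone. Camera with an estimated correlation, camera on ranks and the directional test fry were run beside it. The rule named Aifm1, then up to 10 changed genes per direction with no overlap between the genotypes, filled up by the smallest unadjusted p among genes with at least a 1.5-fold difference, then up to 4 genes with the smallest p in each list, and conventional markers, of which Omp, Gap43, Krt5, Cyp2g1, Cd68, Sod1 and Sod2 are described. Not every gene this rule allows is reported here. Igha, Chil4, Cngb1, Cct4, Cd99l2, Cldn34c1, Atp10d, Mpo, Ppbp, C1qa, Adgre1, Mrc1 and Laptm5 were named after their values were seen. Of these, Cngb1, Mpo, C1qa, Adgre1, Mrc1 and Laptm5 are list members as well.

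The alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median scaling, limma without an intensity trend or with robust moderation, array weights, the mean over a gene's probe sets, probe sets with the suffixes _s_at and _x_at left out, every probe set tested on its own, other thresholds, the replicate number as a block, and each array left out in turn. A neutrophil list without Chil3 was added after seeing the data.

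The procedure was tested on 10 simulated data sets of 13219 genes for the Harlequin against control comparison, each with 200 changed genes. It called 69.6% of genes changed by a log2 of 1, 95.2% of those changed by 2 and 99.2% of those changed by 3, and 6% of all calls were false. In a simulated data set with 1 of 31 lists shifted by a log2 of -0.5, camera with the preset correlation called that list and 0 others. These simulations held no correlation between genes. Each simulated set for the gene test held 200 changed genes, while 4 genes passed in the real comparison. The unadjusted p needed to pass becomes stricter as fewer genes change. The shares called above therefore do not tell what share of such changes the real comparison could find.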

Results

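RNA levels were measured in olfactory epithelium microdissected from 3 male Harlequin mice (Hq/Y) and 3 male littermate controls (+/Y), all 6 months old. Harlequin is a mutation of Aifm1 (formerly Pdcd8), the X-linked gene of apoptosis-inducing factor, a mitochondrial flavoprotein required for normal levels of respiratory chain complex I. The stated purpose was to relate gene expression to the neurodegeneration under oxidative stress seen in this mutant. The strain name in the labels also differed between the groups, and a difference in strain background would coincide with the genotype. Each mouse was profiled on 1 Affymetrix array of 45101 probe sets. The median probe set signal was 109.6, 113.4 and 113.2 on the Harlequin arrays and 107.9, 116.1 and 119.7 on the control arrays, after scaling to the same trimmed mean of 500. The ratio of 3' to 5' Gapdh signal, a measure of RNA integrity, was 0.729 to 0.79 in Harlequin and 0.74 to 0.846 in controls. Pearson correlations across genes were 0.973 to 0.981 between arrays of 1 genotype and 0.971 to 0.982 between arrays of different genotypes, where genes are not independent replicates. With 3 arrays per genotype, the number of arrays limits the precision of every comparison.

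The first comparison asked whether the mutated gene itself was lower in the mutants. Aifm1 fell in Harlequin epithelium to 21.2% of the control signal. Its single probe set gave 255.9 ± 69.0 (SD, n = 3) in Harlequin and 1208 ± 69.5 (SD, n = 3) in controls. All 3 mutants, at 335.4, 221.1 and 211.2, lay far below the controls, at 1239.9, 1255.6 and 1128.2. The log2 fold change was -2.20 (SE 0.18), with a limma adjusted p of 0.0158 over all genes tested. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. The call was lost without control replicate 1 (adjusted p = 0.097), 2 (0.0616) or 3 (0.068), at log2 fold changes of -2.18, -2.17 and -2.25, and also without an intensity trend in the variance model (adjusted p = 0.0887).

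The second comparison asked which other genes differed between the genotypes. Besides Aifm1, 3 genes changed. Chil3, a chitinase-like protein secreted by macrophages and neutrophils, rose 4.60-fold, from 426.8 ± 145 in controls to 1963 ± 261 in Harlequin (SD, n = 3; log2 fold change 2.20, SE 0.23, adjusted p = 0.0315). Azgp1, which encodes the secreted zinc-alpha-2-glycoprotein, fell from 1782 ± 171 to 644.5 ± 97.1 (log2 fold change -1.45, SE 0.14, adjusted p = 0.0243). Pdxdc1, a pyridoxal-dependent decarboxylase domain protein, rose from 1399 ± 97.0 to 2706 ± 198 at its brightest probe set (log2 fold change 0.94, SE 0.10, adjusted p = 0.0315). Its other 3 probe sets lay the opposite way, with log2 differences of -2.05, -1.26 and -0.35, and the mean over its probe sets gave -0.68.

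**Figure D1:**
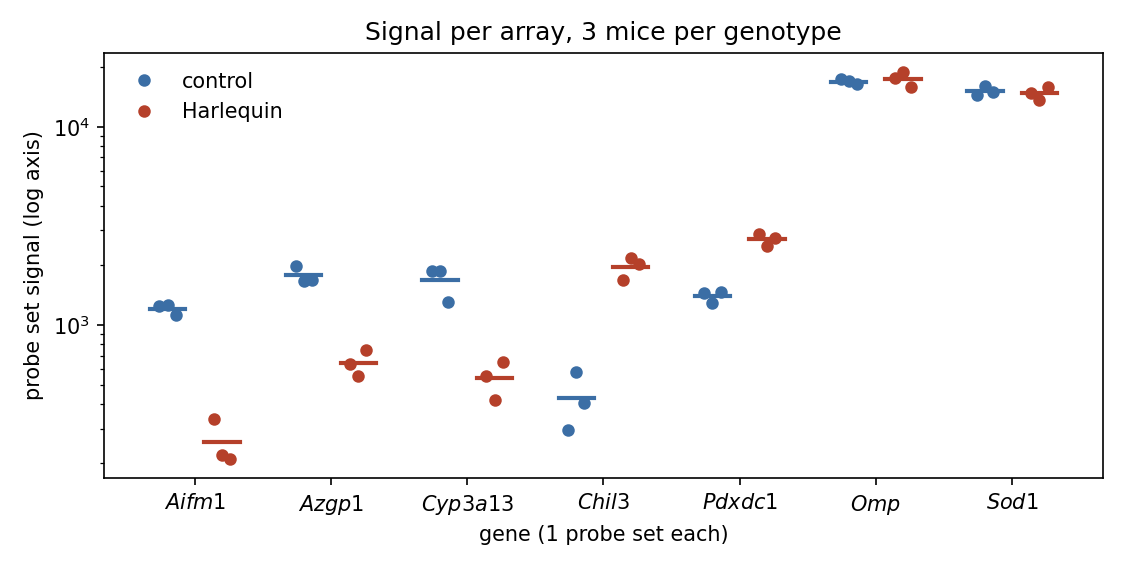
Probe set signal on a log axis for 7 genes, 1 probe set each, with a point for each of the 3 mice per genotype and a bar at the mean. Aifm1, Azgp1 and Cyp3a13 lay lower in every Harlequin mouse than in every control and Chil3 and Pdxdc1 higher, while the genotypes overlapped for Omp and Sod1.

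Over 13219 genes tested, the 4 genes at an adjusted p under 0.05 were 2 higher and 2 lower in Harlequin. At an unadjusted p under 0.05 there were 605 genes, 264 higher and 341 lower, where 661 would be expected with no difference at all. Genes whose 3 Harlequin values all lay on one side of the 3 control values numbered 1369, or 10.4%, against the 10% that chance gives. No gene passed in limma without control replicate 1, without control replicate 3 or without an intensity trend, where 702, 696 and 643 genes had an unadjusted p under 0.05. Without Harlequin replicate 1 only Aifm1 passed, without Harlequin replicate 2 Aifm1 and Igha passed, without Harlequin replicate 3 Aifm1, Azgp1 and Cldn34c1, and without control replicate 2 Chil3 and Atp10d.

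Several genes ranked next without passing the test over all genes. Cyp3a13, a cytochrome P450 of drug and steroid oxidation, was at 539.0 ± 116 in Harlequin and 1683 ± 330 in controls (log2 difference -1.62, adjusted p = 0.0765). In limma with array weights it passed (adjusted p = 0.0355). It neighbours Azgp1 among the measured genes of chromosome 5. Among genes with higher signal in all 3 Harlequin mice were Alas2, the first enzyme of erythroid haem synthesis (log2 difference 1.52, adjusted p = 0.75), the red cell membrane protein Ermap (0.83), the adipocyte hormone Adipoq (1.17), the aspartic protease Ctse (1.41), the endocytic protein Amph (0.65), the DNA repair enzyme Parp2 (0.64) and the kinetochore protein Pmf1 (0.73). Slc44a2 was higher at its brightest probe set (0.66), and its other 2 probe sets differed by 0.10 and -0.41. The other probe set of Pmf1, a dim one, differed by -0.41. Lower signal in all 3 Harlequin mice was seen for the actin-associated Palld (-0.63), Phlda1 (-0.67), the lysosomal nuclease Dnase2a (-0.63), the desaturase Scd1 (-0.63), Wfdc18 (-0.63), Lmln (-0.91) and 4933404O12Rik (-0.91). The other probe set of Lmln differed by 0.27. The mean over the probe sets of a gene was 0.89 for Ctse, 0.16 for Pmf1, 0.12 for Slc44a2, -0.32 for Palld and -0.32 for Lmln. The adjusted p of these 15 genes, Cyp3a13 left out, was 0.571 or more.

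The third comparison asked whether groups of genes fixed beforehand as cell type markers and pathways shifted together. In the set test with a preset correlation, 4 of 31 lists shifted upward in Harlequin and 3 downward. Neutrophil and marrow granulocyte markers, cell cycle genes, macrophage markers and B and plasma cell markers moved upward. Fibroblast and matrix genes, markers of olfactory ensheathing and Schwann glia, and secretory products of Bowman and nasal glands moved downward. None of the 7 shifts held when the correlation between genes was estimated from the arrays (adjusted p = 0.668 for each) or in the directional test fry (adjusted p of 0.231 or more). Each list was also scored per array by the mean log2 deviation of its genes from their mean over all arrays. The 95% interval of the genotype difference spanned both signs for all 7 lists. It was -0.69 to 2.06 for neutrophil, -0.21 to 0.585 for cell cycle, -0.19 to 0.56 for macrophage and -0.05 to 0.70 for B cells. It was -1.05 to 0.41 for fibroblast, -0.41 to 0.07 for glial and -0.62 to 0.18 for gland genes. In all 7 lists the scores overlapped between the genotypes.

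Neutrophil and marrow granulocyte markers shifted upward by a median log2 of 0.73 (adjusted p = 0.00217 with the preset correlation, 0.668 as an adjusted p with an estimated correlation), with 9 of 10 measured genes higher. Chil3 was the 1 member that passed, both adjusted over the list alone and over all genes. The neutrophil granule genes Ngp (log2 difference 1.02) and Camp (0.97) and the calcium-binding S100a8 (0.78) were higher on average but did not pass, and leaving out 1 array took them as low as 0.43, 0.32 and 0.19. Without Chil3, a setting chosen after seeing the data, the median was 0.68 and the adjusted p 0.0277, or 0.763 with an estimated correlation. Macrophage markers shifted upward by a median of 0.20 (adjusted p = 0.00548, and adjusted p = 0.668 with an estimated correlation), with 13 of 17 genes higher and 0 passing adjusted over the list alone. Among them the complement genes C1qc and C1qb differed by 0.37 and 0.38, the adaptor Tyrobp by 0.42 and Cd68 by 0.20. The third complement gene of the list, C1qa, differed by -0.029, and Adgre1 (-0.043), Mrc1 (-0.065) and Laptm5 (-0.103) were lower as well. The other 2 probe sets of C1qb differed by -0.03 and 0.14. With 1 array left out C1qb went as low as 0.21, Tyrobp 0.25 and Cd68 0.05. B and plasma cell markers shifted upward by a median of 0.26 (adjusted p = 0.0258, and adjusted p = 0.668 with an estimated correlation), with 7 of 8 higher and 0 passing. Jchain, which joins secreted immunoglobulins, differed by 1.05 (0.76 to 1.45 with 1 array left out) and overlapped between the genotypes. The B cell coactivator Pou2af1 differed by 0.56 (0.35 to 0.71 with 1 array left out). The immunoglobulin A heavy chain gene Igha, chosen after its values were seen and not in the list, differed by 1.43 to 1.46 at its 3 probe sets. Igha did not pass over all genes (limma adjusted p = 0.981). At its brightest probe set Harlequin replicate 2 was at 956.9, against 2504.3 and 2841.9 on the other Harlequin arrays.

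Cell cycle genes shifted upward by a median of 0.20 (adjusted p = 0.00548, and adjusted p = 0.668 with an estimated correlation), with 18 of 20 higher and 0 passing adjusted over the list alone. Cyclin A2, Ccna2, was at 423.8 ± 50.9 in Harlequin and 299.1 ± 29.1 in controls (SD, n = 3; log2 difference 0.48, or 0.30 as the mean over its probe sets), Mki67 differed by 0.47 and Cdk1 by 0.31, and leaving out 1 array took these as low as 0.31 and 0.16. Red cell genes lay in the same direction. Of the erythrocyte list 3 of 11 genes were measured, too few for the set test, and all 3 rose adjusted over the list alone although none passed over all genes. These were Alas2, at 1665 ± 370 against 591.1 ± 227, the anion exchanger Slc4a1, at 1221 ± 352 against 504.3 ± 368, and the carbonic anhydrase Car1, at 305.9 ± 103 against 119.1 ± 87.5, with a median log2 change of 1.47. Leaving out 1 array moved Car1 between 0.85 and 1.96. Scored per array, the erythrocyte list was lowest in control replicate 2 (-1.61) and was higher in control replicate 3 (0.13) than in control replicate 1 (-0.73), while the 3 Harlequin arrays lay at 0.60, 1.05 and 0.55.

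**Figure D2:**
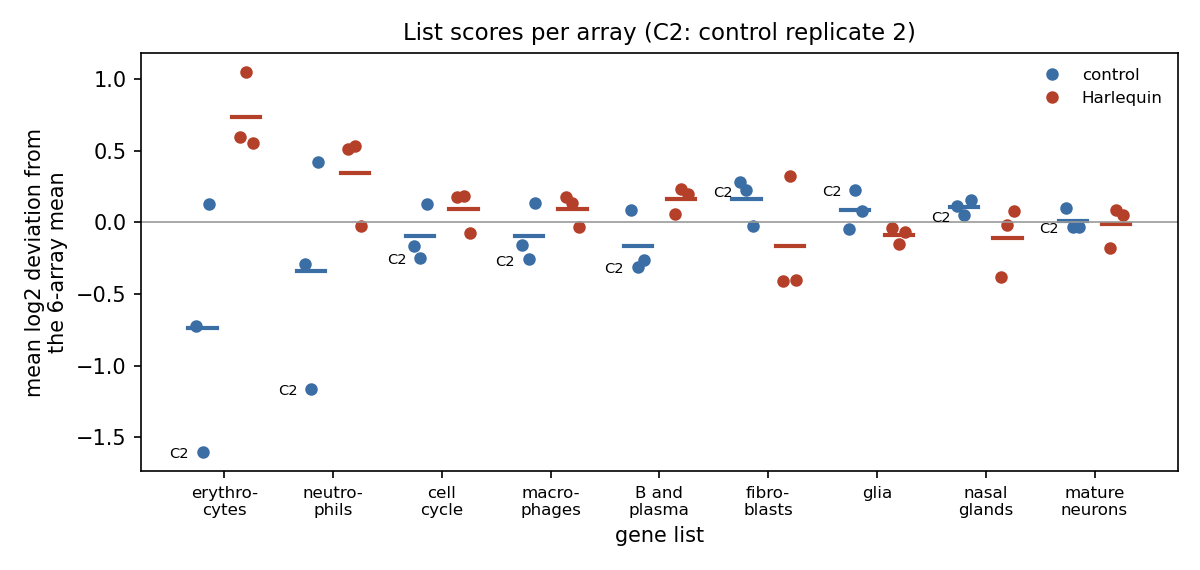
Score of 9 gene lists on each array, as the mean log2 deviation of the list's genes from their mean over the 6 arrays, with points for single mice and bars for genotype means. Control replicate 2, marked C2, was the lowest array for erythrocyte (-1.61), neutrophil (-1.17), cell cycle (-0.24), macrophage (-0.26) and B and plasma cell (-0.31) genes. It was the highest array for glial genes (0.23).

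Fibroblast and matrix genes shifted downward by a median of -0.31 (adjusted p = 0.00554, and adjusted p = 0.668 with an estimated correlation), with 11 of 12 lower and 0 passing adjusted over the list alone. The collagens Col6a1 and Col3a1 differed by -0.52 and -0.77 and the matrix glycoprotein Sparc by -0.55, or -0.36 as the mean over its probe sets. Leaving out 1 array moved Col3a1 between -1.11 and -0.38 and Sparc between -0.81 and -0.36. Harlequin replicate 2, with a list score of 0.33, was the highest of the 6 arrays, above the controls, at 0.29, 0.22 and -0.03, while the other Harlequin arrays lay at -0.41 and -0.40. Markers of ensheathing and Schwann glia shifted downward by a median of -0.17 (adjusted p = 0.00554, and adjusted p = 0.668 with an estimated correlation), with 9 of 12 lower. The calcium-binding S100b, at 1112 ± 30.9 in Harlequin and 1500 ± 140 in controls, and the myelin protein Mbp, at 494.7 ± 54.4 and 769.7 ± 168, fell adjusted over the list alone and did not pass over all genes. The mean over probe sets gave a log2 difference of -0.27 for S100b, against -0.42 at the probe set used. Secretory products of Bowman and nasal glands shifted downward by a median of -0.11 (adjusted p = 0.0277, and adjusted p = 0.668 with an estimated correlation), with 15 of 18 lower and 0 passing. Its members include the lipocalins Lcn11 (-0.27), Obp1a (-0.12) and Obp2a (-0.11) and the urinary protein Mup5 (-0.10). With quantile normalization these differed by -0.24, -0.04, -0.04 and -0.02.

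No list passed without control replicate 2. Without it the neutrophil median was 0.16 (adjusted p = 0.0977), the cell cycle median 0.10 (0.0972), the macrophage median 0.09 (0.10), the B cell median 0.15 (0.102), the fibroblast median -0.27 (0.0972), the glial median -0.10 (0.0972) and the gland median -0.09 (0.102). The neutrophil, cell cycle, macrophage, B cell and glial medians thus shrank, and the fibroblast and gland medians moved less. Without control replicate 3 the neutrophil median was 1.22 (adjusted p = 1.09e-07) and the cell cycle median 0.35 (6.48e-06), but with an estimated correlation 0 lists passed there. Without Harlequin replicate 1 the number of lists was 12, and without Harlequin replicate 3 it was 4, but 0 with an estimated correlation in either case. The fibroblast median was -0.66 (1.44e-08) without Harlequin replicate 2 and -0.51 (0.0112) without control replicate 3, where 0 lists passed with an estimated correlation in either case. Fibroblast genes also lost their call without Harlequin replicate 1 (-0.14, adjusted p = 0.185) or 3 (-0.16, 0.102), cell cycle and macrophage genes without Harlequin replicate 2, and B cell and gland genes without Harlequin replicate 2 or 3 or control replicate 3. The gland call was also lost without the filter (adjusted p = 0.127), with quantile normalization (0.238) and without an intensity trend (0.142), the fibroblast call with array weights (0.0551) and the B cell call on ranks (0.0515).

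**Figure D3:**
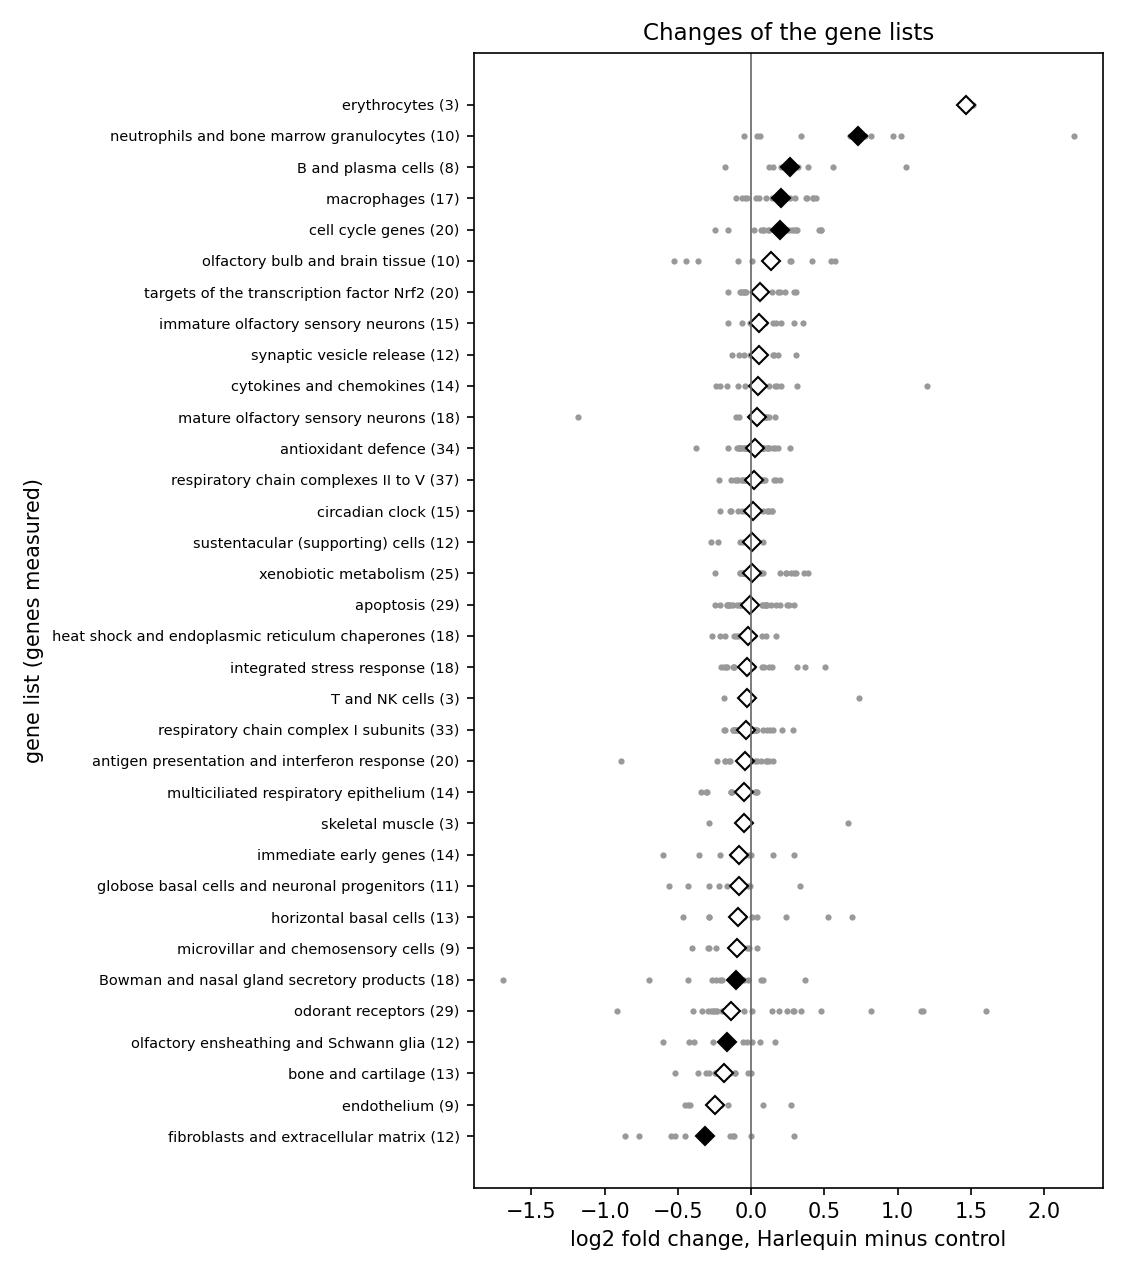
Log2 fold change of each measured gene (grey points) and the median (diamonds) of 34 gene lists, with the number of measured genes in brackets. Black diamonds mark the 7 lists with an adjusted p under 0.05 in the set test with a preset correlation, and the 3 lists with 3 measured genes did not enter that test.

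Neuronal lists did not pass the set test. Markers of mature olfactory sensory neurons had a median difference of 0.04 (adjusted p = 0.396), and Omp, the classical marker of these cells, gave 17460 ± 1475 in Harlequin and 16890 ± 479 in controls (SD, n = 3; log2 difference 0.04, 95% interval -0.12 to 0.21). The cyclic nucleotide-gated channel subunit Cngb1 differed by -1.19 at a dim probe set (47.6 ± 35.4 against 111.1 ± 2.97; -1.59 to -0.66 with 1 array left out) and did not pass. Immature neurons had a median of 0.06 (adjusted p = 0.144), with Gap43 at -0.06 and Crmp1 at 0.35 (0.23 to 0.50 with 1 array left out). Globose basal cells and neuronal progenitors had a median of -0.08 (0.234), horizontal basal cells -0.09 (0.533), with Krt5 at 0.006 and Trp63 at -0.46, and sustentacular cells 0.009 (0.533), with Cyp2g1 at 0.008. The odorant receptors on the array had a median of -0.14 (0.641) and synaptic vesicle genes 0.05 (0.389). Without Harlequin replicate 1, upward shifts passed for mature neurons (median 0.07, adjusted p = 0.043), immature neurons (0.08, 0.0371) and synaptic vesicle genes (0.16, 0.0186), and a downward shift for horizontal basal cells (-0.22, 0.0371). Mature neurons also passed without control replicate 1 (0.09, 0.0383). With an estimated correlation 0 lists passed in either case. In the list of olfactory bulb and brain genes, which did not shift (median 0.14, adjusted p = 0.533), Eomes rose (log2 fold change 0.57) and Reln fell (-0.52) adjusted over the list alone. The mean over probe sets gave -0.12 for Reln.

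Stress and respiratory gene lists did not pass either. The median difference was 0.03 for 34 antioxidant defence genes (adjusted p = 0.533), 0.06 for targets of the transcription factor Nrf2 (0.234), -0.04 for 33 complex I subunits (0.533), 0.02 for 37 subunits of complexes II to V (0.743), -0.006 for 29 apoptosis genes (0.641), -0.03 for the integrated stress response (0.686) and -0.02 for chaperones (0.234). Nrf2 targets passed without Harlequin replicate 2 (median 0.07, adjusted p = 0.0349) and chaperones without Harlequin replicate 1 (-0.09, 0.0371), but 0 lists did with an estimated correlation in either case. Sod1 gave 14750 ± 1098 in Harlequin and 15130 ± 886 in controls (log2 difference -0.04, 95% interval -0.21 to 0.14), and Sod2 gave 4384 ± 201 and 4361 ± 397 (0.01, 95% interval -0.20 to 0.22). Among the members with the lowest p were the complex I subunits Ndufv1 (0.29) and Ndufs7 (0.21), the kinase-like Trib3 (0.37), the thioredoxin reductase Txnrd1 (0.19) and the peroxidase Gpx7 (-0.38), and none passed adjusted over its list alone. Ndufb3 differed by -0.18, Cycs by -0.16, Xiap by -0.14, Ddit3 by 0.31 and Chac1 by 0.51. The mean over probe sets gave 0.18 for Ndufv1, 0.19 for Ddit3 and 0.12 for Xiap. Leaving out 1 array took Ndufb3 to -0.08, Cycs to -0.07, Trib3 to 0.24, Txnrd1 to 0.11, Ddit3 to 0.12 and Chac1 to 0.25 at the least.

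For the remaining lists the medians were -0.09 for microvillar cells (adjusted p = 0.0697), -0.25 for endothelium (0.0846), -0.05 for multiciliated epithelium (0.144), 0.008 for xenobiotic metabolism (0.533), 0.05 for cytokines and chemokines (0.533), -0.04 for antigen presentation (0.533), -0.08 for immediate early genes (0.382) and 0.01 for the circadian clock (0.769). All 13 bone and cartilage genes were lower in Harlequin (median -0.18, adjusted p = 0.144), in the direction of the fibroblast list. Microvillar cells passed downward without the filter (median -0.18, adjusted p = 0.0305) and with a filter at the 60th percentile (-0.17, 0.0407), but 0 lists passed there with an estimated correlation. Endothelium did so without the filter (-0.26, 0.0214), with median scaling (-0.22, 0.0475) and without control replicate 1 (-0.28, 0.028), multiciliated epithelium without Harlequin replicate 1 (-0.24, 6.14e-07), and bone and cartilage without Harlequin replicate 2 (-0.44, 0.00509). Under each of these settings 0 lists passed with an estimated correlation. T and NK cell and skeletal muscle markers had 3 measured genes each, with medians of -0.03 and -0.05 and means of 0.17 and 0.11. Among the lists tested, median and mean differed in sign for mature neurons (mean -0.03), sustentacular cells (-0.04), horizontal basal cells (0.001), odorant receptors (0.08), the integrated stress response (0.02) and apoptosis (0.001). The set test pointed upward for mature neurons and the integrated stress response and downward for the other 4.

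**Figure D4:**
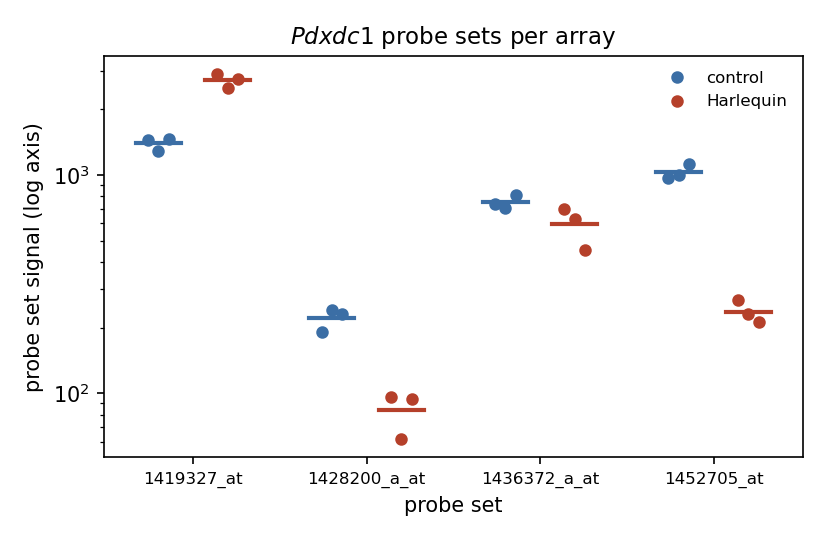
Signal on a log axis of the 4 Pdxdc1 probe sets in each mouse, with bars at genotype means. Probe set 1419327_at was higher in all 3 Harlequin mice, 1452705_at and 1428200_a_at were lower in all 3, and 1436372_a_at was lower in each Harlequin mouse than in the 3 controls.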

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

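Several probe sets outside the 1 used per gene differed between the genotypes when each of 27022 probe sets was tested on its own in limma. Testing each probe set on its own was planned. The tests of dim signal and of the splits of the arrays for the Pdxdc1 pattern were chosen after the result was seen.

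Pdxdc1 probe set 1452705_at fell by 2.05 on the log2 scale (adjusted p = 0.0039), from 1031 ± 82.1 in controls to 237.0 ± 28.8 in Harlequin (SD, n = 3), while 1419327_at rose by 0.94 (adjusted p = 0.0355). Noise in dim probe sets is argued against for 1452705_at and 1419327_at, whose means were 237.0 or more in both genotypes, against a filter signal of 61.1. The dimmest probe set that moved apart, 1428200_a_at, reached 3.62 times that signal in its brighter group but had a mean of 84.3 in Harlequin. The genotypes did not overlap, which adds little because these probe sets were picked for an unadjusted p under 0.01 between the genotypes. Genes with probe sets in opposite directions at an unadjusted p under 0.01 were counted over all 10 splits of the 6 arrays. With 3 arrays on each side, 5 of the 10 splits had at least 1 such gene (1 in the real split, at most 2 in another). That cutoff is looser than the limma adjusted p of 0.0039 and 0.0355 at the 2 Pdxdc1 probe sets. The count therefore does not tell how often other splits give so strong a pair, and 10 splits are too few for a share under 0.05. A change in transcript structure and a strain variant under some of the probes both stay open, and neither was tested because probe sequences were not used here. The genotype itself stays open as well.

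Cd99l2 probe set 1456746_a_at fell by 2.09 (adjusted p = 0.0116) on the log2 scale, from 474.0 in controls to 100.9 in Harlequin, whereas the brightest Cd99l2 probe set differed by 0.38 (adjusted p = 0.985). Of its other 2 probe sets, 1456747_x_at differed by -0.91 (adjusted p = 0.96) and 1423966_at by 0.20, so that the probe sets of Cd99l2 lay in opposite directions like those of Pdxdc1. Cd99l2 is not in the count of 1 gene above because the unadjusted p of its brightest probe set lay just above the cutoff of 0.01, and in a fit without the filter it lay below it. Cct4 probe set 1456082_x_at fell by 1.04 (adjusted p = 0.0386), whereas the brightest Cct4 probe set, at 5459 ± 98.0 in Harlequin and 5859 ± 281 in controls, differed by -0.10 (adjusted p = 0.985).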

How the results depend on the processing

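Every alternative was fixed before the data were examined except the neutrophil list without Chil3, with the preset and with an estimated correlation. Outside the alternatives named here, Aifm1 and the counts of changed genes and shifted lists kept their direction and their side of the threshold. The log2 fold change of Aifm1 ranged from -2.27 to -2.01 over 12 alternatives, with an adjusted p of 0.0061 to 0.0887. It was -2.20 without an intensity trend (adjusted p = 0.0887), and leaving out 1 array moved it between -2.40 and -2.08. The number of changed genes was 0 without an intensity trend, 7 probe sets of 6 genes with every probe set tested on its own, 53 at an unadjusted p under 0.01 with a 1.5-fold difference (17 higher, 36 lower), and 0 to 3 with 1 array left out. With array weights it was 5, with Cyp3a13 added. The number of shifted lists was 0 with an estimated correlation, 0 with fry, 6 with camera on ranks and 0 to 12 with 1 array left out. The labels do not say which mice shared a litter or whether the replicate numbers pair the arrays. The deviations of arrays with the same number correlated at -0.237, -0.03 and 0.058, which shows no sign of pairing but cannot exclude it. With the replicate number as a block, 0 genes and 7 lists passed, or 0 lists with an estimated correlation, and Aifm1 was at -2.20 (adjusted p = 0.0605). The red cell list had 5 measured genes without the filter and then passed the set test (median 1.43, adjusted p = 0.00192, and adjusted p = 0.695 with an estimated correlation). The B cell list had too few genes for the test with a filter at the 60th percentile.

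The mean over probe sets turned Pdxdc1 to -0.68, Cd99l2 to -0.60, Xiap to 0.12, complexes II to V to -0.009 and progenitors to 0.035. Krt5 turned to -0.002 with quantile normalization and -0.054 with array weights, which also turned Cyp2g1 to -0.003 and complexes II to V to 0. The bulb list turned to -0.084 without the filter. With 1 array left out, these turned: Krt5 (-0.272 to 0.194), Sod2 (-0.049 to 0.079), Sod1 (-0.089 to 0.018), Omp (-0.011 to 0.111), Gap43 (-0.217 to 0.046), Cyp2g1 (-0.034 to 0.028), Mpo (-0.35 to 1.057), antioxidant genes (-0.039 to 0.058), complexes II to V (-0.022 to 0.038), complex I (-0.05 to 0.013), odorant receptors (-0.163 to 0.047), xenobiotic metabolism (-0.046 to 0.066), apoptosis (-0.073 to 0.027), horizontal basal cells (-0.224 to 0.097), ciliated cells (-0.242 to 0.024), chaperones (-0.088 to 0.022), immediate early genes (-0.138 to 0.056), antigen presentation (-0.14 to -0.001), bulb genes (0.049 to 0.275), cytokines (-0.02 to 0.202), clock genes (-0.019 to 0.034), integrated stress (-0.054 to 0.057) and sustentacular cells (-0.031 to 0.009). The direction of a list is that of its set test, so its median need not change sign. The cause was not tested. Signals near 61.1, where the filter lies, carry little information.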

Other observations

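Chil4, a chitinase-like gene next to Chil3 on chromosome 3, lay the opposite way from it. It gave 1696 ± 1630 in Harlequin and 9141 ± 2047 in controls (SD, n = 3), a log2 difference of -3.06 that did not pass over all genes (adjusted p = 0.981) and ranged from -3.91 to -2.03 with 1 array left out, with Harlequin arrays at 1388.2, 3458.5 and 241.6 and control arrays at 8538.0, 11421.3 and 7462.8. Among 3443 probe sets that name several genes or none, 0 passed in limma, with 158 at an unadjusted p under 0.05. The first of them, 1433438_x_at, was at 231.7 ± 20.4 in Harlequin and 39.5 ± 17.2 in controls (adjusted p = 0.0673).

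Of the tests in this part, the comparison of red cell with primary granule genes, the comparisons over both lists and the random draws of neighbouring genes were chosen after the result was seen.

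Red cell and granulocyte genes were higher on average in Harlequin, and more blood or marrow in the dissected tissue could raise both. None of the red cell genes passed over all genes, and Slc4a1 overlapped between the genotypes. The red cell list could be tested only without the filter, and its shift was lost with an estimated correlation (adjusted p = 0.695). Of the granulocyte genes only Chil3 passed, and the shift of their list was lost with an estimated correlation (adjusted p = 0.668) and without control replicate 2 (median 0.16, adjusted p = 0.0977). Its score was higher in control replicate 3 (0.43) than in Harlequin replicate 3 (-0.02). Primary granule genes, made in marrow, changed by a mean log2 of 0.09 (95% interval -2.39 to 2.58, 4 genes, with Mpo at 1055 ± 553 in Harlequin and 992.0 ± 904 in controls), which is 1.38 below the change of the erythrocyte list (95% interval 0.03 to 2.73). The 8 platelet genes, among them Ppbp at 1139 ± 637 and 929.6 ± 923, changed by a mean of 0.33 (95% interval -0.96 to 1.63), which is 1.14 below it (95% interval 0.67 to 1.61). Such gaps were set as evidence against more marrow or more blood, for blood before the result was seen. They rest, however, on the 3 red cell genes measured, which are the top of the pattern and include no globin gene. Over the 13 genes of the erythrocyte and neutrophil lists the gap was 0.78 for primary granule genes (95% interval -0.42 to 1.97) and 0.53 for platelet genes (95% interval -0.01 to 1.08), so neither more marrow nor more blood is excluded. An added list of 29 erythroid genes had a median of 0.27 with 27 of 29 higher. Its camera p was 1.09e-07 with the preset correlation and 0.0803 with an estimated one, and the 95% interval of its mean change was -0.14 to 0.69. The list had left out genes already seen near the top of the ranking, so its lower median excludes nothing. More marrow, more blood, a shift of red cell genes as a class, red cells with more of their young, RNA-rich forms and the genotype stay open.

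Genes with small p-values lay near each other more often than random genes did. Among 110 genes at an unadjusted p under 0.01, with Azgp1, Cyp3a13, Chil3 and Chil4 left out, 10 pairs lay within 5 measured genes of each other, against a median of 4 in 10000 random draws (permutation p = 0.0176). The count includes the pair of Zfp280c with Aifm1, the mutated gene itself. Paired genes lay in opposite directions there and also for Tpm3 with Rps27, Srsf11 with Wls and Fut10 with Tex15. Neighbouring pairs might mark strain segments that differ between the genotypes, but neighbouring genes varied together under other groupings too. With Azgp1, Cyp3a13, Chil3 and Chil4 kept, the real split gave 12 pairs. Among as many top genes, 4 of the 10 splits of the 6 arrays gave 12 or more pairs, the real split included, and another split at most 16. Strain segments and such shared variation cannot be told apart, since no strain genotypes were used here. The strain name in the labels differs along with the genotype, while the titles call the controls littermates. Around Aifm1, 3 of the 50 nearest measured genes on the X chromosome had an unadjusted p under 0.05, or 6%, against 4.57% of other genes (Fisher's exact test, one-sided p = 0.403). This was set beforehand as evidence against a segment carried along with Aifm1, but 50 genes are too few for a p above the threshold to show that none differ, so it stays open.

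Whether the calls exceed chance was examined by splitting the 6 arrays into 3 and 3 in all 10 ways, which is too few for a share under 0.05. The real split called 4 genes and the highest other split 4, so that 2 of the 10 splits had as many. It called 7 lists and the highest other split 10, and 5 of the 10 splits had as many. The share of variance between the groups was 20.2% in the real split and 15.8% to 24.2% in the others.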
